A study of Magallana gigas with 9 samples.

How the data were processed

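Polyadenylated RNA was measured by RNA sequencing in whole larvae of the Pacific oyster (Magallana gigas, also known as Crassostrea gigas), a marine bivalve. Per the labels' protocols, culture lasted 9 h at 22 °C in artificial sea water, RNA was extracted with Trizol, and libraries were made with the ScriptSeq v2 kit. The labels give 3 groups of 3 samples, namely untreated larvae (control), larvae given all-trans retinoic acid (RA) and larvae given a compound written as Ro-41-5232 (Ro), which the series title calls an inhibitor of retinoic acid. The treatment protocol gives 1 µM once, in front of both compounds, and it was read here as the dose of each. The start and length of exposure, the solvent, and whether the 3 samples of a group were separate cultures or spawnings are not given in the sources used here. All p-values therefore measure only the spread between these samples, which may be technical.

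The authors deposited 1 table per library in the format of RSEM, the only tool that the submitters' processing notes name, without a version. Each table lists 159452 components and their 311494 transcripts. The identifiers, such as comp457189_c0, have the form that a de novo transcript assembly gives, in which a component stands for a group of assembled transcripts treated as 1 gene. The assembler, its settings, the aligner and any filter are not given in the sources used here. Per the file headers, the deposited values are expected counts (reads assigned to each component by RSEM and summed over its transcripts, with no normalization), TPM values (transcript abundance normalized for length and for the library's total), FPKM values and lengths. Between 3.16% and 5.26% of the component values per library, those at 0 included, were not whole within 0.005. RSEM divides reads among the transcripts they match. Reads divided within 1 component add up to whole numbers again, so fractions can remain where a read matches several components. The TPM columns were used only in an alternative test, and the authors' FPKM columns were not tested.

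The files do not pair components with gene names. None of the component identifiers (0 of 159452) was found in the RefSeq gene table of the oyster, and transcript sequences were not used here. The 26 lists of pathway, cell-type and stress genes fixed in advance, which included retinoid pathway, homeobox, shell formation, cilia, muscle and neural genes and germline markers, could not be given members (0 of 26 had any), so the planned tests of gene lists were not run. Components are therefore reported by identifier, with their length and number of assembled transcripts. Genome positions are not given for the same reason. A gene can be split over several components, alleles of 1 gene can form separate components, and near-identical genes can share 1, so that counts of components are not counts of genes.

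Expected counts were rounded to whole numbers. Components with too few counts were removed with filterByExpr of edgeR (version 4.0.16), leaving 22149 components that held 97.8% to 99.4% of each library's counts. Their median length was 1246 bases, against 293 bases over all components. Library sizes were scaled by TMM. The 9 libraries entered 1 quasi-likelihood model with a coefficient per group (glmQLFit and glmQLFTest), from which RA against control, Ro against control and Ro against RA were tested, all two-sided. P-values were adjusted by the Benjamini-Hochberg method over the components tested, and a component was called changed at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the test's F value, and 95% intervals used 11.1 degrees of freedom. Levels are given as CPM (counts scaled to a fixed total) on TMM-scaled library sizes, as mean ± SD over 3 libraries. Shares of a library's counts were compared by exact permutation tests, two-sided, for which 3 samples against 3 cannot give a p below 0.1.

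The components named in the text were chosen by a rule set before the data were examined. For identifiers without names it takes, per comparison, the 2 higher and the 2 lower components with the smallest p among those with a mean of at least 1 CPM over the groups compared. The 3 most abundant components were singled out after their values were seen. The design, this rule and the alternatives were also fixed before the data were examined, except for 4 alternatives and the tests named in the closing section. The alternatives were other filters, RLE and upper-quartile scaling, DESeq2 (version 1.42.0), limma-voom and limma (version 3.58.1) on log2(TPM + 1), fits of only the groups compared, a replicate block, a minimum fold change and leaving out each library. The 4 added later left out the libraries that stood apart, left out the 3 most abundant components, removed each library's trend with length, and weighted libraries by quality.

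Depth ranged from 8184630 expected counts (Ro replicate 1) to 16982015 (control replicate 2). Without the 3 most abundant components the totals ranged from 5589417 (control replicate 3) to 10876652 (Ro replicate 2). The procedure was tested on simulated counts for the 22149 components, drawn from the real means, library sizes and spreads with 200 components changed. These 200 were taken only from the better expressed components, so recovery among weakly expressed ones was not tested. For Ro against control, 4 of 50 components changed 2-fold were recovered, 37 of 50 changed 4-fold and 46 of 50 changed 8-fold. For RA against control the numbers were 4, 42 and 48 of 50, and for Ro against RA they were 4, 34 and 45 of 50. False calls were 9 of 143 for Ro against control, 15 of 156 for RA against control and 3 of 134 for Ro against RA. The simulated libraries of a group differed only by independent noise, which the real ones did not.

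Both treated groups were compared with the same 3 control libraries. Unchanged groups with the spread of each real group were therefore simulated against controls in 30 draws, and the values these gave are printed beside the overlap and covariance observed. Equal changes in both treated groups were simulated in 10 further draws, with the Ro means given to the RA libraries. No pair of libraries looked like repeat deposits of 1 library. The closest, Ro replicates 2 and 3, had a chi-square of 12.9 per degree of freedom over components with at least 20 counts in the pair, where sampling noise alone gives about 1.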

Results

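RNA from whole oyster larvae was sequenced in 9 libraries, 3 each from untreated larvae, larvae given RA and larvae given Ro. RA is a vitamin A derivative that acts in vertebrates through nuclear receptors. Library totals were 11580952, 16982015 and 10728316 expected counts for control replicates 1 to 3, 9888450, 11468469 and 11626189 for RA, and 8184630, 15940833 and 10709460 for Ro. The 3 RA libraries were alike, with pairwise correlations of log2 CPM across components of 0.953 to 0.968. In the control group, replicate 3 correlated at 0.743 and 0.830 with replicates 1 and 2, which correlated at 0.913 with each other. In the Ro group, replicate 1 correlated at 0.876 and 0.880 with replicates 2 and 3, which correlated at 0.966. Components are not independent replicates, and these values describe the libraries only. The first principal component of the tested components held 37.7% of the variance. Its 2 highest libraries were control replicate 3 (141) and Ro replicate 1 (110), and the other 7 lay between -110 and 8.26.

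A small number of components held a large part of each library. The 10 most abundant took between 29.6% (Ro replicate 1) and 51.9% (control replicate 3) of the counts. The most abundant on average, comp451157_c1 (mean length 15170 bases, 4 transcripts), took 18.4% ± 4.39 of the counts in controls, 21.3% ± 2.78 in RA and 20.6% ± 1.52 in Ro (SD, n = 3 each). The next, comp446326_c0 (3701 bases, 22 transcripts), took 17.9% ± 5.03 in controls, 6.35% ± 3.13 in RA and 6.20% ± 3.38 in Ro. The share of comp448482_c0 (2621 bases, 11 transcripts) was 10.3% ± 2.51 in controls, 4.52% ± 1.99 in RA and 4.45% ± 2.18 in Ro. These 3 were singled out after their values were seen. Together, comp446326_c0 and comp448482_c0 took between 21.9% and 35.8% of the counts in the 3 controls and between 4.31% and 15.8% in the 6 treated libraries. The groups did not overlap, and the exact permutation test gave p = 0.1 for RA against control and for Ro against control, the smallest value that 3 libraries against 3 can give. The combined share was 10.9% ± 5.09 in RA and 10.6% ± 5.55 in Ro (exact permutation p = 1), a test that could not have passed 0.05 with 3 libraries a group.

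**Figure D1:**
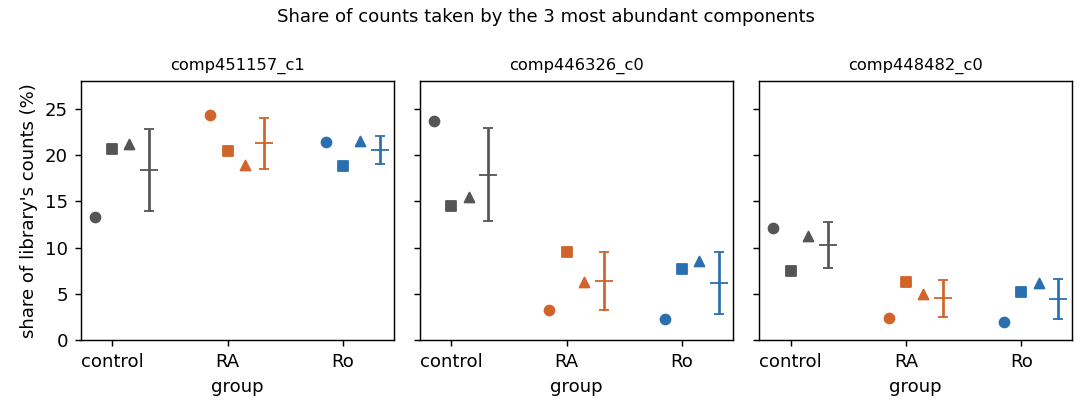
Share of each library's counts, in percent, taken by the 3 most abundant components in the control, RA and Ro groups. Points are libraries (circle, square and triangle for replicates 1, 2 and 3) and bars are mean ± SD (n = 3). For comp446326_c0 and comp448482_c0 the 3 controls lie above all 6 treated libraries, while comp451157_c1 takes 13.3% to 24.4% of the counts in all 9.

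In the edgeR quasi-likelihood test, which works on TMM-scaled counts, comp446326_c0 had a log2 fold change of -1.90 ± 0.50 (SE) for Ro against control, with an adjusted p of 0.041, and of -1.97 ± 0.50 for RA against control, with an adjusted p of 0.21. The call for Ro did not hold without either of the libraries control replicate 1 (adjusted p = 0.10) and control replicate 2 (0.0698), without any 1 RA library (0.0523, 0.0603 and 0.0928 without replicates 1, 2 and 3), or without any 1 Ro library (0.0919, 0.133 and 0.0659 without replicates 1, 2 and 3), and its adjusted p ranged from 9.77e-11 to 0.133 over 21 alternatives, of which 11 did not pass. The values for comp448482_c0 were -1.61 ± 0.47 for Ro (adjusted p = 0.062) and -1.70 ± 0.47 for RA (adjusted p = 0.27). Its fall with Ro was smaller, at -1.02, without control replicate 3 and Ro replicate 1 (adjusted p = 0.17 by edgeR) and with quality weights (0.11 by limma-voom). Some alternatives did call these 3 falls. For comp446326_c0 with RA the adjusted p was 0.0035 by DESeq2, 0.024 by limma-voom with quality weights and 1.89e-09 by edgeR with no filter (range over 21 alternatives 1.89e-09 to 0.998). For comp448482_c0 it was, with Ro, 0.0040 by DESeq2, 0.032 by limma-voom and 2.27e-07 by edgeR with no filter (range 2.27e-07 to 0.181), and with RA 0.012 by DESeq2 and 3.73e-06 by edgeR with no filter (range 3.73e-06 to 0.998). Between Ro and RA, the 95% interval of the log2 difference was -1.0 to 1.1 for comp446326_c0 and -0.93 to 1.1 for comp448482_c0.

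RA-treated larvae were compared with untreated larvae, whose solvent is not given in the sources used here. In RA, 17 components were higher and 13 lower of the 22149 tested (edgeR quasi-likelihood test, adjusted p under 0.05). The changes were large, with a median log2 fold change of 3.54 among the higher (range 1.58 to 4.52) and -2.74 among the lower (range -3.46 to -1.61), and in all 30 the 3 RA libraries did not overlap the 3 controls. Over all tested components, 15.8% showed no overlap, where chance gives 10%. The 30 were called by a test of these same libraries, which favours no overlap, so this count adds no support to the calls. The rise of comp454721_c2 (934 bases, 9 transcripts) was 15.1-fold, from 11.7 ± 2.96 CPM in controls to 178 ± 27.9 CPM in RA (SD, n = 3 each), a log2 fold change of 3.92 ± 0.33 (SE) with an adjusted p of 0.0024 by edgeR. The level of comp457014_c0 (1935 bases, 3 transcripts) rose 13.4-fold, from 17.2 ± 8.48 to 233 ± 21.7 CPM (log2 3.75 ± 0.34, adjusted p = 0.0025 by edgeR). Among components that fell, comp459994_c0 (3445 bases, 4 transcripts) went from 149 ± 39.7 to 33.8 ± 5.67 CPM, a log2 fold change of -2.14 ± 0.25 (adjusted p = 0.011 by edgeR). The level of comp448737_c0 (709 bases, 7 transcripts) went from 57.0 ± 22 to 5.15 ± 1.24 CPM, a log2 fold change of -3.46 ± 0.43 (adjusted p = 0.014 by edgeR).

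Runs without 1 library leave 2 in its group and also change the components tested. The number of components called for RA moved widely in these runs. It was 2 without any 1 of RA replicates 1, 2 and 3, 11 without Ro replicate 2, 14 without Ro replicate 3 and 64 without control replicate 2 (49 higher, 15 lower), and it was 107 (51 higher, 56 lower) without both control replicate 3 and Ro replicate 1, which kept all 30 components. The balance of higher and lower calls also turned without control replicate 1 (12 higher, 21 lower). The falls of comp459994_c0 and comp448737_c0 did not pass the threshold without any 1 RA library, with adjusted p of 0.170, 0.0954 and 0.115 for comp459994_c0 and of 0.194, 0.201 and 0.115 for comp448737_c0 without RA replicates 1, 2 and 3 (range over 22 alternatives 4.31e-13 to 0.170 and 4.86e-14 to 0.201), and the fall of comp459994_c0 also did not pass under limma on log2(TPM + 1) (0.0944) or in a fit of only RA and control (0.0620). Under limma on log2(TPM + 1), which centres the libraries differently (median over all components 0.36 against -0.10), 81.1% of 90 called components were higher, against 56.7% of 30 here.

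Larvae given Ro, the compound named as an inhibitor, were compared with the same untreated larvae. In Ro, 1826 components differed from controls (8.24% of those tested), of which 721 were higher and 1105 lower than in controls (edgeR, adjusted p under 0.05), a balance that turned to 816 higher and 704 lower without control replicate 2. A change of more than 4-fold was seen in 690 of them, 203 higher and 487 lower. In 1823 of the 1826 the 3 Ro libraries did not overlap the 3 controls, which the selection by a test of these libraries favours. Over all tested components 24.2% showed no overlap, where chance gives 10%. The smallest p was that of comp457189_c0 (2668 bases, 11 transcripts), which had 11, 33 and 10 counts in the 3 controls and 5029, 6046 and 4301 in the 3 Ro libraries. Its level rose from 1.57 ± 0.59 to 433 ± 105 CPM (SD, n = 3 each), a log2 fold change of 8.06 ± 0.37 (adjusted p = 4.08e-06 by edgeR), and was 1.56 ± 0.26 CPM in RA. The level of comp451130_c0 (1451 bases, 2 transcripts) rose 42.3-fold, from 2.92 ± 0.026 to 124 ± 22 CPM (log2 5.4 ± 0.27, adjusted p = 4.88e-06 by edgeR). The level of comp452500_c0 (1162 bases, 17 transcripts) fell from 142 ± 28.7 to 8.81 ± 1.72 CPM, a log2 fold change of -4.00 ± 0.28 (adjusted p = 8.74e-05 by edgeR). The level of comp449420_c0 (928 bases, 3 transcripts) fell from 92.0 ± 41 to 1.49 ± 0.76 CPM, a log2 fold change of -5.98 ± 0.48 (adjusted p = 0.000164 by edgeR).

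Most calls lay among the better covered components. With the components divided into 5 classes of about equal size by mean abundance, 1.24% were called in the lowest class (up to 1.35 CPM) and 15.2% in the highest (27.8 CPM and over). The count of calls was 1039, 1073 and 1028 without RA replicates 1, 2 and 3, which enter only through the shared estimate of spread and the filter, and 943, 714 and 866 without Ro replicates 1, 2 and 3. Without both control replicate 3 and Ro replicate 1 it was 2058 (781 higher, 1277 lower), of which 1445 were among the 1826. Under limma on log2(TPM + 1) 62.1% of 1924 called components were higher, against 39.5% here, with a median over all components of 0.24 against -0.05.

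Ro against RA, at the same nominal dose, compares the 2 compounds directly. Ro and RA differed in 578 components, 236 higher and 342 lower in Ro (edgeR, adjusted p under 0.05). In all 578 the 3 libraries of each group did not overlap, which the selection by a test of these libraries favours. Over all tested components 28.2% showed no overlap, where chance gives 10%. Of the 236 that were higher in Ro, 220 were also higher in Ro than in controls. Of the 342 that were lower in Ro, 286 were also lower than in controls. Both comparisons use the same 3 Ro libraries, which favours this agreement, and it was not compared with what noise gives. The smallest p was again that of comp457189_c0 (log2 8.11 ± 0.37, adjusted p = 3.72e-06 by edgeR), which stood at the control level in RA (log2 -0.05, 95% interval -0.79 to 0.70). The level of comp450397_c0 (979 bases, 9 transcripts) was 6.19 ± 0.87 CPM in controls, 6.83 ± 1.09 in RA and 160 ± 21.6 in Ro, 23.4-fold higher in Ro than in RA (log2 4.55 ± 0.25, adjusted p = 1.20e-05 by edgeR). In the other direction, comp458577_c0 (1854 bases, 8 transcripts) stood at 52.8 ± 15.8 CPM in controls, 372 ± 55.7 in RA and 39.2 ± 10.8 in Ro, a log2 difference of -3.25 ± 0.31 between Ro and RA (adjusted p = 0.000724 by edgeR). The level of comp454721_c2, at 178 CPM in RA, was 20.2 ± 7.39 CPM in Ro (log2 difference -3.14 ± 0.31, adjusted p = 0.0010 by edgeR).

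The number of components that differed between Ro and RA lay between 120 (without RA replicate 2) and 153 (without RA replicate 1) when any 1 RA library was left out, and was 240, 187 and 193 without Ro replicates 1, 2 and 3, where the balance turned without Ro replicate 2 (102 higher, 85 lower), and 1269 without control replicate 3. Without both control replicate 3 and Ro replicate 1 it was 1089 (404 higher, 685 lower) and kept 577 of the 578. Under limma on log2(TPM + 1) 27.1% of 693 called components were higher in Ro, against 40.8% here, with a median over all components of -0.13 against 0.06.

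**Figure D2:**
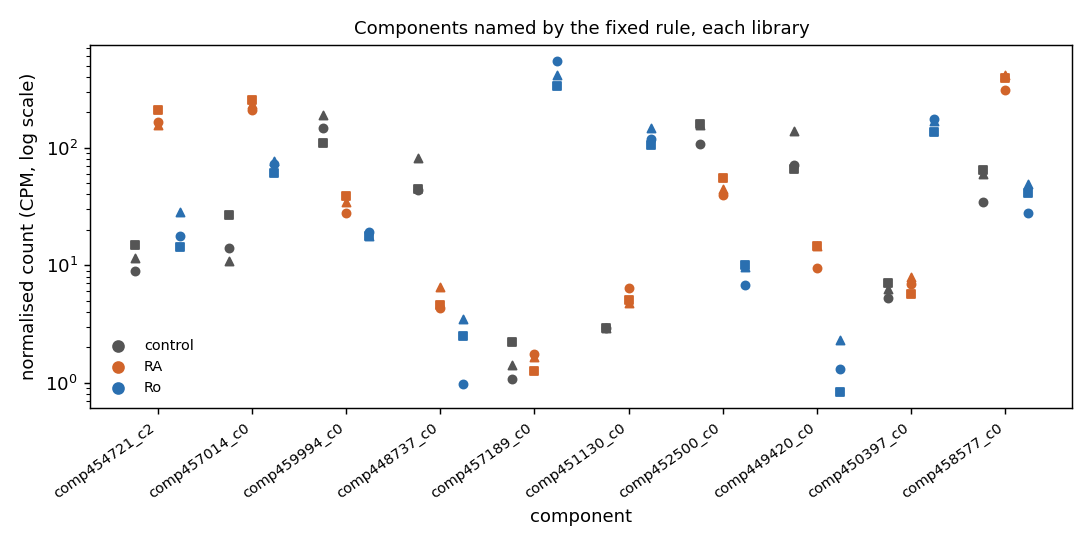
Normalised counts (CPM, log axis) in each library of the 10 components named by the fixed rule, with control in grey, RA in orange and Ro in blue, and replicates 1, 2 and 3 as circle, square and triangle. For comp457189_c0 the RA libraries lie with the controls near 1.6 CPM and the Ro libraries between 338 and 546 CPM, while for comp458577_c0 the Ro libraries lie with the controls.

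The responses to RA and Ro were then set side by side. Of the 30 components called for RA, 20 were also called for Ro in the same direction (8 higher, 12 lower) and 0 in the opposite direction. Independent lists of these sizes would share 0.553 higher and 0.649 lower components and 1.27 in opposite directions, and 30 simulated draws of unchanged groups against controls gave 0 in each case, but these made only 0.033 (RA) and 0.17 (Ro) calls per draw, so they do not measure what shared controls add to overlapping calls. The number of shared calls was 1 without any 1 RA library, 6 without Ro replicate 2, 9 without Ro replicate 3, 58 without control replicate 2 and 31 without control replicate 3, and 76 without both control replicate 3 and Ro replicate 1. Of the 13 components lower in RA than in controls, 12 were also called lower in Ro, and by the test between the 2 compounds 6 of the 13 were lower in Ro than in RA and 1 was higher. Of the 17 components higher in RA than in controls, 10 were lower in Ro than in RA, 1 was higher, and 9 were not called for Ro against control. The fall of comp459994_c0 was -2.14 with RA and -3.03 ± 0.26 with Ro (adjusted p = 0.000223 by edgeR), and the difference between the compounds, -0.89 (95% interval -1.43 to -0.35), did not pass (adjusted p = 0.098 by edgeR). For comp449420_c0 the log2 fold changes were -2.84 ± 0.40 with RA (adjusted p = 0.024) and -5.98 with Ro, and the difference of -3.14 ± 0.44 passed (adjusted p = 0.0042 by edgeR). The rise of comp457014_c0 was 3.75 with RA and 2.02 ± 0.31 with Ro (adjusted p = 0.0032), and Ro was lower than RA by -1.73 ± 0.31 (adjusted p = 0.015 by edgeR).

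Of the 1826 components called for Ro, 1622 (88.8%) had a fold change of the same sign in RA, 631 of the 721 higher and 991 of the 1105 lower. This share rests on shared controls and on components selected by their Ro change. With components called without 1 control, and RA compared with that control alone, the share was 70.6%, 75.7% and 59.5% for control replicates 1, 2 and 3. The RA changes were smaller, with a median of 0.54 against 1.52 for Ro among the higher and of -0.70 against -1.86 among the lower. Selection by the Ro change enlarges the Ro medians, and these values are not corrected for it. For 506 of the 1826 the test between Ro and RA was also passed in the same direction, and 1 was higher than in controls yet below RA. The other 1319 were not called between Ro and RA at this threshold. The 506 include components with an RA change of the opposite sign, and both tests use the same 3 Ro libraries, which favours agreement. The 1319 rest on a spread estimated over all 3 groups. A fit of only Ro and RA called 2114 components between them, against 578 here. The 506 became 131, 102 and 106 without RA replicates 1, 2 and 3, 206, 162 and 168 without Ro replicates 1, 2 and 3, and 1015 without control replicate 3. Across all tested components the log2 fold changes of RA and Ro correlated at 0.61, and 74.7% had the same sign. Both comparisons use the same 3 controls, and unchanged groups simulated against controls gave a mean correlation of 0.75 and 78.8% with the same sign. The covariance was 0.498, against a simulated mean of 0.444 (range 0.431 to 0.457), a difference of 0.0537. The covariance was 0.810, 1.03 and 1.26 without control replicates 1, 2 and 3, and 0.621 without both control replicate 3 and Ro replicate 1. The cause of these differences was not tested, and the simulation was not repeated for them. With 3 controls, no part of them could be split off with 2 libraries on each side, so part of the excess in shared calls may come from the shared controls.

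**Figure D3:**
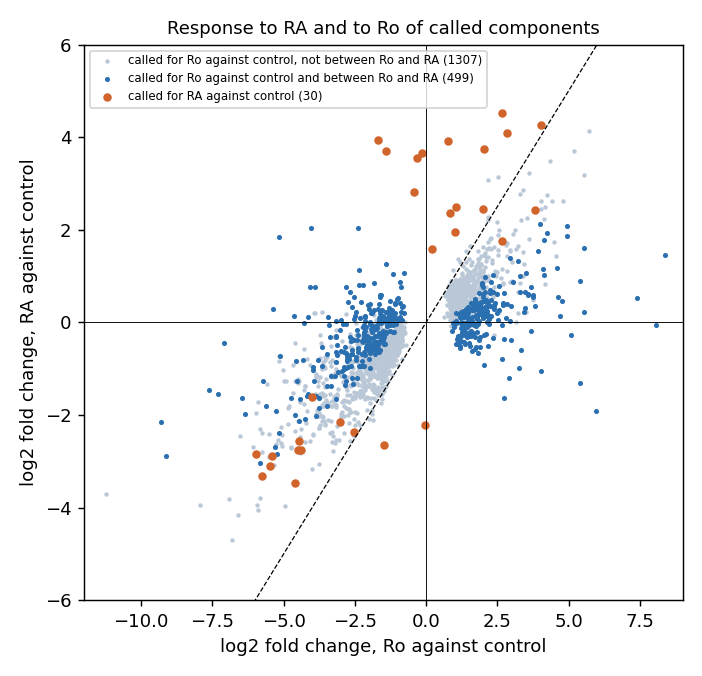
Log2 fold change for RA against control (vertical axis) and for Ro against control (horizontal axis) of called components. Shown are components called for Ro only against control (1307, grey), called for Ro against control and between Ro and RA (499, blue), or called for RA against control (30, orange). The grey and blue sets leave out components called for RA. The dashed line marks equal change. Most grey and blue points lie nearer to 0 on the RA axis than on the Ro axis, which their selection by a Ro call without an RA call favours.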

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

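Leaving out the libraries that stood apart, leaving out the 3 most abundant components, removing the length trend and quality weights were chosen after seeing the data, and the other alternatives before. In the comparisons they were named for, the 10 components named by the rule kept their sign in all 22 alternatives, and all stayed past the threshold except comp459994_c0 (17 of 22) and comp448737_c0 (19 of 22) for RA. The share of components called for Ro with the same sign in RA lay between 88.1% and 93.1%. The numbers of calls moved more. For RA against control, 30 components became 252 with no filter on low counts, 484 with DESeq2, 71 with limma-voom, 90 with limma on log2(TPM + 1), 9 in a fit of only the groups compared, 107 without both libraries that stood apart and 343 with limma-voom and sample quality weights. More of the RA calls were lower than higher with no filter (137 of 252), DESeq2 (314 of 484), limma-voom (40 of 71), quality weights (243 of 343) and without the libraries that stood apart (56 of 107), against 13 of 30. For Ro against control, 1826 became 2992 with DESeq2 and 863 in a fit of only the groups compared. For Ro against RA, 578 became 1445 with DESeq2, 2114 in a fit of only these groups, 1089 without the libraries that stood apart and 2847 with quality weights. Components called for both compounds in the same direction numbered 20 here, 176 with no filter, 365 with DESeq2, 51 with limma-voom, 56 on log2(TPM + 1), 3 with only the groups compared, 76 without the libraries that stood apart and 252 with quality weights. Fits of only the groups compared leave out the other group's spread and test fewer components. In them Ro against RA had more calls (2114) than Ro against control (863), the reverse of the main fit (578 and 1826). Quality weights gave control replicates 3 and 1 and Ro replicate 1 the lowest weights (0.236, 0.386 and 0.441). The cause was not tested for the other changes. Leaving out 1 library at a time gave 2 (without RA replicate 1) to 64 (without control replicate 2) calls for RA, 714 (without Ro replicate 2) to 2431 (without control replicate 3) for Ro, 120 (without RA replicate 2) to 1269 (without control replicate 3) for Ro against RA, and 1 (without RA replicate 1) to 58 (without control replicate 2) shared calls. The covariance of the 2 responses was 0.498, and 0.468 (without Ro replicate 2) to 1.26 (without control replicate 3) over these runs, which also change the components tested, and 1.92 with no filter. The replicate numbers are shared by the 3 groups. Only 3 of 9 same-numbered pairs of libraries had deviations that correlated above 0.1 (range -0.41 to 0.31). In addition, 0 of 9 libraries correlated best with its own number in both other groups, so the numbers were not taken to pair the samples. Between RA and Ro alone the same-numbered pairs correlated at 0.18, 0.31 and 0.030 for replicates 1, 2 and 3, so a pairing of these groups is not excluded. A fit with the replicate number as a block called 17 components for RA (8 higher, 9 lower, 14 of them among the 30), 1168 for Ro, 335 for Ro against RA and 11 shared, and it called comp448482_c0 for Ro (adjusted p = 0.037 by edgeR). The small fold change of comp451157_c1 reversed on log2(TPM + 1) (0.22 for RA and 0.060 for Ro) and, for Ro, without the libraries that stood apart (0.0050). The tests of gene lists were not run, since no component could be given a name. In simulated data about 4 of 50 changes of 2-fold were found in each comparison, all of them placed in better expressed components. Recovery among weakly expressed components, and the part that depth plays in it, was not tested.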

Other observations

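The tests of the axis from control to Ro and of the covariance over all components were chosen after the results were seen. So was the test of components called for Ro and also, in the same direction, between Ro and RA. The same holds for the tests of the Ro libraries left out of the calls and of the 6 treated libraries against the 3 controls. So were the fits without the 3 most abundant components, without the libraries that stood apart, with the length trend removed or with quality weights. For the other tests the predictions were written before their results were seen. Those on control replicate 3, Ro replicate 1 and the 3 most abundant components nonetheless name libraries or components picked after the data were seen.

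Some components were close to absent in 1 group. Counting those with at most 3 counts in total over the 3 libraries of a group and at least 10 counts in each library of the other, 31 were near absent in Ro and present in controls, 19 were near absent in Ro and present in RA, 12 were near absent in controls and present in Ro, and 4 were near absent in RA and present in Ro. For RA and control the numbers were 1 (near absent in controls) and 0. Totals differ between groups, and these counts have no test. Among the 578 components that differed between Ro and RA, 144 lay above the control in RA and below it in Ro, and 94 lay below it in RA and above it in Ro, by the signs of fold changes that were not all past the threshold.

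The first pattern is that RA and a compound named as its inhibitor had fold changes against the same controls that were mostly of the same sign. Over all tested components the correlation could come from the shared controls, since unchanged groups gave 89.2% of the observed covariance, but with components divided into 5 classes by abundance they gave more than was observed in the 2 lowest and 0.131 of an observed 0.325 in the highest. An axis from 2 controls to the Ro libraries was built on components called without the remaining control. The RA libraries lay at 0.319 to 0.518 of the way and the held-out control at 0.150 to 0.254. In each of the 3 turns the lowest RA library exceeded the held-out control by at least 0.169, which goes against shared controls as the whole cause. The 3 turns reuse the same libraries and the gap was not compared with what noise gives, so this is weak evidence. A count of signs against 1 held-out control gave 59.5% (control replicate 3) to 75.7% (control replicate 2) and decided nothing. A difference of the untreated larvae from both treated cultures that acts alike on both, such as a solvent, is argued against as the whole cause of the Ro changes. Of the components called for Ro, 27.7% were also called between Ro and RA in the same direction (12.6%, 9.51% and 10.3% without RA replicates 1, 2 and 3, and 41.8% without control replicate 3). Such a difference was predicted to leave at most 5%. Both tests use the same 3 Ro libraries, so noise in these can raise the share. The share includes components whose RA change had the opposite sign to the Ro change. The sign was the same in 1622 of all 1826, and in 1288 of the 1319 not called between Ro and RA. In components called without 1 Ro library and not called between Ro and RA, the median change of each RA library was 0.353 to 0.481 of that of the Ro library left out (9 ratios). Over the 1319 such components of all libraries the ratio was 0.453. Selection by the Ro change gave 0.883 to 0.905 in simulations with equal changes. These selected 3188 components on average and drew libraries with independent noise only, so they may understate what the selection does in the real data. Open for the shared direction are the shared controls, since the evidence against them is weak, and a solvent or handling difference. The solvent or handling difference could be of equal size with a further response to Ro, or of unequal size. A response to both compounds is open as a hypothesis.

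The second pattern is that control replicate 3 and Ro replicate 1 stood apart from their groups. Fewer distinct RNA molecules in these libraries are a candidate explanation: of components expected at 5 or more counts, 6.09% in control replicate 3 and 3.83% in Ro replicate 1 had 0 counts, against at most 2.49% in the other 7 libraries, and at a common depth of 5589417 counts they had 10017 and 11544 components with 1 or 2 counts, against 20004 or more. Swapped labels are argued against by components called without these 2 libraries, on which control replicate 3 lay at 0.0677 and Ro replicate 1 at 1.11 on the axis from control (0) to Ro (1). Control replicate 3 was higher in the shortest of 5 length classes of components (median log2 0.58) and lower in the longest (-0.33), but with each library's length trend removed the better of the 2 still had a mean correlation of 0.841 with the other libraries, below the 0.851 of the next lowest, control replicate 1. No biological explanation was tested.

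The third pattern is the larger share of comp446326_c0 and comp448482_c0 in controls. An effect of these shares on the other calls through normalization is argued against as the whole cause, since 95.3% of the components called for Ro were still called with the 3 most abundant components left out. The balance of the Ro calls did move with scaling. It was 640 higher and 1228 lower without these components and 619 and 1254 under RLE scaling, against 721 and 1105 in the main fit. The 3 controls against the 6 treated libraries gave an exact permutation p of 0.0119, the smallest value possible, but these 2 components were picked because their shares were seen to be higher in controls, so this p is no evidence of a difference. A difference in RNA selection or carry-over between control and treated libraries cannot be told apart from an effect of treatment, because the libraries with low shares are the treated ones and no component has a name.

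Other splits of the 6 libraries of each comparison were tried. In each comparison 1 of 10 splits, the real one, gave as many calls as the real groups, and the highest count of the other 9 was 0 by edgeR against 30 for RA, 1826 for Ro and 578 for Ro against RA. At an unadjusted p under 0.05 the highest other split had 2265 components for RA against 2086 in the real one, 3626 for Ro against 4745, and 348 for Ro against RA against 2736. The other tools were not run on these splits. With 10 splits the share cannot fall below 0.05.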
